A study of Homo sapiens with 5 samples.

How the data were processed

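The series holds 5 arrays of human embryonic stem cell derivatives sorted by flow cytometry. Groups were taken from the source names in the labels (CD61+, CXCR4+ and CXCR4+/CD61-) and replicate numbers from the titles. The deposited value table gives log2 expression per probe set, made with RMA per the submitters' processing notes, which also name GCOS, Affymetrix Expression Console and the build hg19 without versions. RMA corrects the background, sets the arrays that are processed together to 1 common distribution and summarises the probes of a set on the log2 scale. The arrays of replicate 1 and replicate 2 do not share a distribution, and whether they were processed together is not given in the sources used here. Values of 1 array therefore compare directly only with arrays of the same number. No background signal per probe was used here, so levels near 3 to 5 on the log2 scale are read as close to the floor.

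Of the probe sets in the table, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 were unnamed here. Entrez identifiers of 19429 single-symbol probe sets matched the reference table, and 0 symbols needed an update. The 18417 distinct genes were each represented by the probe set with the highest mean over the 5 arrays, which mattered for 769 genes with more than 1 probe set. Of per-sample value columns, 0 were left out. Genes read only by probe sets with several symbols are not reported here.

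Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 group means, 2 residual degrees of freedom, no level filter), and adjusted p-values are Benjamini-Hochberg over all genes with a threshold of 0.05. Each test was fitted over all 5 arrays so that the groups share 1 estimate of the spread. Gene lists were tested with limma's camera (preset correlation 0.01) against all other genes, adjusted over the 30 lists, and again with an estimated correlation and with fry. Many lists share members, so their calls are not independent. All p-values are two-sided. The comparisons, their tests, the lists, the main alternatives and the rule for named genes were fixed before the data were examined.

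The rule named ITGB3, CXCR4, ITGAV and ITGA2B on every array. For each comparison of CD61+ cells it then named the 12 genes with the highest and the 12 with the lowest difference (5 and 5 for CXCR4+ against CXCR4+/CD61- cells) among genes past the test, with arrays of the groups not overlapping and the higher group mean in the upper 60 percent of genes. Places left empty were filled by size of the difference from genes with the same overlap and level conditions, and those genes are named as not past the test. It also named up to 4 members of each list with the largest difference between CD61+ and CXCR4+ cells. Clone, LOC and orf names, probe sets with several or no symbols and genes of the sex chromosomes' sex-specific kind were not named by size. Fewer list members are printed than the rule allows. Which of them to print was settled after their directions with each array left out had been seen: of 130 eligible genes in the comparison of CD61+ and CXCR4+ cells 54 turned direction at least once, and of 71 genes printed in the report 16 did. The genes COL12A1, GLIPR1, CAV1, NTS, SOX17 and FOXA2, and values of list members between CD61+ and CXCR4+/CD61- cells, were chosen after seeing the data.

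Because arrays of the same number shared a distribution, each difference was also computed within replicate 1 and within replicate 2. Counts of genes past a fold in both replicates were set against the product of the counts in each replicate divided by the genes tested. The 2 replicate pairs share no array. The alternatives were a filter on level, the mean of all probe sets of a symbol, all rows of the table, quantile normalization, median centring, an intensity trend, a robust prior, only the groups compared, pooled reference groups, a replicate block, a looser threshold, a fold minimum and each array left out in turn. A replicate block after quantile normalization and one with an intensity trend were added after seeing the data, as were all within-replicate values.

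The functions were tested on simulated data, with 10 simulations of 18417 genes, 200 of them changed, built from the fitted means and replicate shift. The spread of each gene was first taken from its moderated variance. That draw gave many false calls, and a second draw, from the prior distribution that limma fits, was added after this was seen. Both are given. For CD61+ against CXCR4+ cells without a replicate shift, limma made 23.8 false calls per simulation with the first draw and 8.8 with the second, and recovered 96.1% and 38.6% of genes changed by a log2 value of 1 and 100% and 93.5% of those changed by 2. With the replicate shift of the data it made 0 false calls and recovered 0% at log2 values of 1 and 2 with both draws, and 63.0% and 33.3% at 4. With a replicate block it recovered 100% and 94.0% at 2, with 66.8 false calls per simulation with the first draw and 9.1 with the second. For CD61+ against CXCR4+/CD61- cells with the shift it recovered 0% at each size with both draws, and with the block 100% and 75.1% at 2 with 65.5 and 9.3 false calls. The fit without a block was chosen before the values were seen, since no label says what the replicate number marks. In the simulations for CD61+ against CXCR4+ cells, camera called a list shifted by 0.6 in 10 of 10 simulations and 0 of 300 lists that were not shifted, with either draw. Simulated genes varied independently, so this does not test camera on genes that vary together. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 made the tables and figures.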

Results

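Human embryonic stem cells of the lines HUES-2 and H9 were grown on mouse feeder cells, taken through the first stage of an endoderm differentiation protocol, and separated by flow cytometry on 2 surface antigens. CXCR4 is a chemokine receptor widely used to sort definitive endoderm, and CD61 is integrin beta-3, the product of ITGB3. RNA from 5 sorted samples was hybridised to Affymetrix arrays: 2 of CD61+ cells, 2 of CXCR4+ cells and 1 of CXCR4+/CD61- cells. The series asked how CD61+ cells differ in mRNA from CXCR4+ cells and from CXCR4+/CD61- cells. The labels call the replicates biological and do not state separate cultures, so limma p-values measure only the spread between these samples. Camera p-values with the preset correlation set the genes of a list against other genes and do not measure spread between samples. Which line each sample came from, and whether CD61+ cells were also gated on CXCR4, is not given in the sources used here. The CXCR4+ label, unlike CXCR4+/CD61-, does not exclude CD61+ cells, so the CXCR4+ sort may hold some of them.

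In all, 18417 genes were tested. The arrays numbered 2 had a higher and narrower distribution than those numbered 1. The median log2 value was 5.15 for CD61+ replicate 1 and 5.12 for CXCR4+ replicate 1, against 5.82, 5.79 and 5.84 for the CD61+, CXCR4+ and CXCR4+/CD61- arrays of replicate 2. Sorted values differed by 0.0224 to 0.0356 log2 on average between arrays of the same number and by 0.4353 to 0.4798 between arrays of different numbers. Differences are therefore also given between arrays of the same number, as values of 1 array against 1 with no test.

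CD61+ cells carried more ITGB3 mRNA than CXCR4+ cells in both replicates. The ITGB3 level was 7.23 ± 0.60 (SD, n = 2) in CD61+ cells and 5.67 ± 0.62 (SD, n = 2) in CXCR4+ cells, and the CXCR4+/CD61- array gave 5.38. Between arrays of the same number the ITGB3 difference was 1.57 in replicate 1 and 1.54 in replicate 2, or 2.97-fold and 2.90-fold. ITGAV, the alpha-v partner of CD61 in the vitronectin receptor, was higher by 0.53 and 0.48. ITGA2B, the platelet partner, differed by -0.29 and 0.01 and by -0.14 over both replicates, which turned to 0.24 without CD61+ replicate 1 and 0.09 without CXCR4+ replicate 2. CXCR4 itself was at 11.12 and 11.11 in CD61+ cells, 11.29 and 11.28 in CXCR4+ cells and 11.29 in CXCR4+/CD61- cells, so that the CD61+ sort held CXCR4 mRNA at close to the level of the other sorts.

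Several genes of connective tissue matrix had higher levels in CD61+ than in CXCR4+ cells of both replicates. Lumican (LUM), a collagen-binding proteoglycan, was at 5.79 and 5.67 in CD61+ cells and 3.61 and 3.59 in CXCR4+ cells, where it lay close to the floor, so its difference of 2.13 ± 0.31 (SE) is not an exact size. HAPLN1, SNAI2, COL6A3, LOX, THBS2, ITGA11, COL12A1 and GLIPR1, and of the genes given further on HAND1, VTCN1, ITGB6, MMP9, PAX3 and DCX, were also below 5 in CXCR4+ cells of replicate 1. GRHL2 was below 5 in those of replicate 2. Their differences are not exact sizes either. Other differences in replicate 1 and replicate 2 were 2.98 and 1.57 for TGFBI, a matrix protein induced by TGF-beta, and 2.40 and 1.48 for HAPLN1, a hyaluronan link protein. They were 1.81 and 1.60 for SNAI2, a transcription factor of epithelial-mesenchymal transition, and 2.14 and 1.23 for ANXA1, an annexin. GCNT4, a glycosyltransferase, was at 6.55 and 7.37 in CD61+ cells and at 5.05 and 6.39 in CXCR4+ cells. In all, 15 genes were at least 2-fold higher in CD61+ cells of both replicates, against 0.475 if the replicates were independent, and 0 were at least 2-fold lower in both. Of these 15, LUM, TGFBI, HAPLN1, SNAI2, ANXA1, ITGB3, COL6A3, LOX, COL1A1, CDH11 and the collagen-binding integrin ITGA11 fall under the rule for named genes. The others, COL12A1, GLIPR1, CAV1 and NTS, were chosen after their values were seen. At 1.5-fold, 57 genes were higher in both replicates against 10.1 if independent, 3 were lower in both against 3.77, and 43 were higher in replicate 1 and lower in replicate 2 against 12.8. Across all 18417 genes, which are not independent replicates, the differences of the replicates were hardly related (Pearson r = -0.06, Spearman rho = -0.13).

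**Figure D1:**
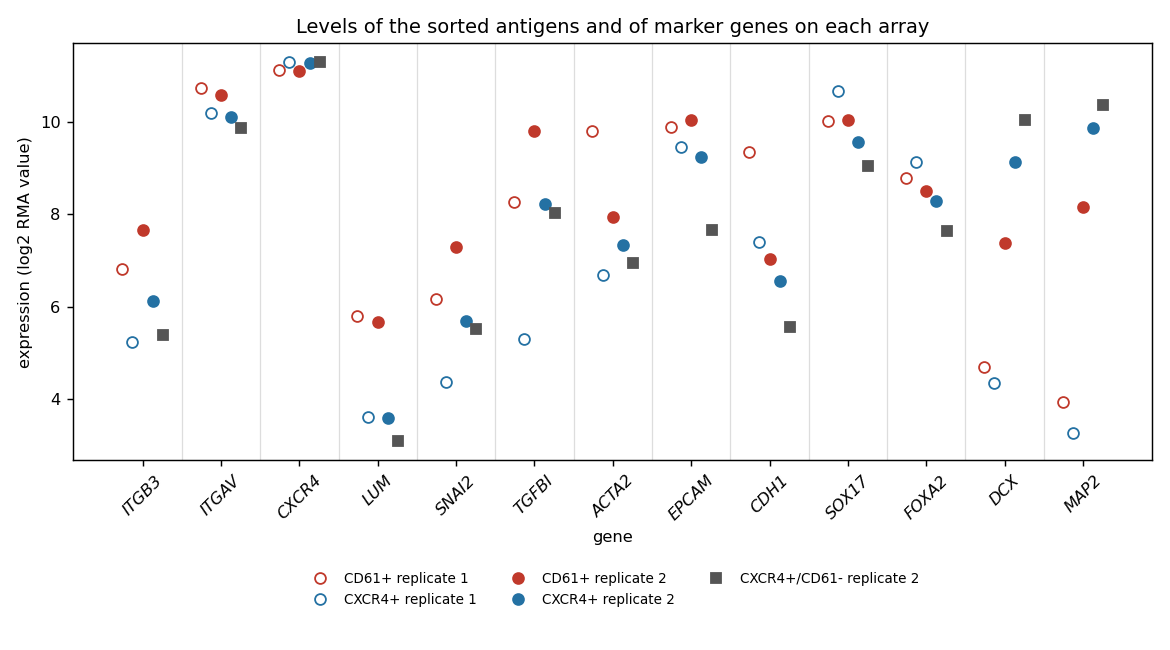
Log2 expression of 13 genes on each of the 5 arrays, with 1 point per array, open circles for replicate 1, filled circles for replicate 2 and a square for the single CXCR4+/CD61- array. ITGB3, LUM, SNAI2 and TGFBI lie higher in CD61+ than in CXCR4+ cells of both replicates, while DCX and MAP2 lie below 5 on the replicate 1 arrays and above 7 on the replicate 2 arrays.

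Another set of genes was far higher in CD61+ cells of replicate 1 and little higher in replicate 2. Smooth muscle actin ACTA2 differed by 3.12 and 0.62, cardiac actin ACTC1 by 2.77 and 0.35 and enteric smooth muscle actin ACTG2 by 1.91 and 0.70. The hypoxia-inducible factor EPAS1 differed by 3.21 and 0.37, and ITGA2, the alpha-2 subunit of a collagen receptor, by 2.50 and 0.32. On the lower side, among genes whose arrays did not overlap between the groups, the differences were smaller. Some genes with overlapping arrays lay lower, such as GLRA1 at -1.23 over both replicates, with 0.07 in replicate 1 and -2.53 in replicate 2. Within replicate 2, 199 genes were at least 2-fold lower and 76 at least 2-fold higher in CD61+ cells. In replicate 1 these counts were 2 and 115. ZNF667-AS1, a noncoding RNA, was lower by 0.83 and 1.28 on the log2 scale, that is -0.83 and -1.28 as CD61+ minus CXCR4+. The apolipoprotein gene APOC1 differed by -0.93 and -0.42, the tubulin acetyltransferase gene ATAT1 by -0.40 and -0.46, and the respiratory complex subunit gene NDUFA1 by -0.41 and -0.51. The guanine nucleotide exchange factor PREX1 (-0.28 and -1.03), the retrotransposon-derived gene PEG10 (-0.18 and -1.03), GREB1 (-0.22 and -0.83) and the activin receptor ACVR2B (-0.15 and -0.68) differed more in replicate 2. TMA7, ERCC6L2, CAMTA1 and ASMTL completed the 12 lowest that met the rule for named genes, with means between -0.42 and -0.51. By limma on all 5 arrays, 0 of 18417 genes passed an adjusted p of 0.05 and the smallest adjusted p was 1, so all genes named for this comparison are named by size and not as past the test. At an unadjusted p under 0.05, limma gave 18 genes against 921 by chance, in a fit that counts the gap between replicates as spread. In simulated data with the replicate shift of these arrays, limma recovered 0% of genes set to differ by a log2 value of 2, and 33.3% or 63.0% of those set to differ by 4, depending on how the spread of each gene was drawn. With single arrays left out, which makes the replicates unequal between groups, the count was 4 without CD61+ replicate 1, 114 without CXCR4+ replicate 1, 2 without CD61+ replicate 2 and 31 without CXCR4+ replicate 2.

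Of 30 gene lists fixed before the data were examined, 15 differed from other genes between CD61+ and CXCR4+ cells by camera with a preset correlation, 14 upward and 1 downward. With an estimated correlation 0 of the 30 were called (lowest adjusted p 0.538), and 0 with the rotation test fry (lowest 0.999). The matrix list of fibroblasts and mesenchymal cells led. Its 20 measured members had a median difference of 0.59, with 0.29 in replicate 1 and 0.62 in replicate 2, and 15 of the 20 were higher in both replicates (camera adjusted p = 2.2e-19, 0.538 with an estimated correlation). COL6A3 differed by 1.41 and 2.38, lysyl oxidase (LOX) by 1.19 and 1.47, and COL1A1 by 1.38 and 1.11. LUM had an adjusted p of 0.00801 adjusted over the list alone and of 1 over all genes. Ligands of integrin alpha-v beta-3 had a median of 0.52, with 0.28 and 0.19 within the replicates and 11 of 18 members higher in both (camera adjusted p = 3.07e-10, 0.538 with an estimated correlation). Among them osteopontin (SPP1) differed by 2.69 and -0.04, THBS1 by 1.46 and 0.86, THBS2 by 0.39 and 1.41, and EDIL3 by 1.78 and 0.00. The matrix list alone among the 15 kept its call with each array left out in turn, with a highest adjusted p of 0.0191. The ligand list lost it without CXCR4+ replicate 1 (adjusted p = 0.0666). Leaving out 1 array of either group brings the gap between the replicates into the difference, so these changes do not measure stability alone. Replicate 2 minus replicate 1 had a median of 0.97 over the matrix list and 0.41 over all genes. Over both replicates the differences turned to -0.33 for COL1A1, -0.12 for THBS2 and -0.78 for EDIL3 without CXCR4+ replicate 1, and to -0.19 for COL1A1 and -0.63 for THBS2 without CD61+ replicate 2.

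Genes of epithelial junctions and keratins had an upward call that turned downward without CD61+ replicate 1 or CXCR4+ replicate 2, with a median of 0.22, values of 0.30 and 0.22 within the replicates and 14 of 20 members higher in both (camera adjusted p = 3.07e-10, 0.538 with an estimated correlation). E-cadherin (CDH1) differed by 1.96 and 0.47, GRHL2 by 1.62 and 0.19, EPCAM by 0.44 and 0.78, and CLDN6 by 0.45 and 0.68. The list of epithelial-mesenchymal transition had a median of 0.17, with 0.22 and 0.15 within the replicates and 11 of 18 members higher in both (camera adjusted p = 1.46e-09, 0.538 with an estimated correlation). CDH11 differed by 2.06 and 1.10, MMP9 by 1.52 and 0.41, and fibronectin (FN1) by 1.33 and 0.41. Smooth muscle genes had medians of 0.22 and 0.09 within the replicates (camera adjusted p = 4.07e-08, 0.538 with an estimated correlation), with CALD1 at 1.18 and 0.39 and CNN1 at 0.22 and 0.55. Integrins had medians of 0.22 and 0.01 (camera adjusted p = 1.07e-05, 0.538 with an estimated correlation), with ITGA11 at 1.12 and 1.08 and ITGB6 at 1.03 and 0.12. The integrin list and the list of surface markers hold ITGB3, the gene of the sorted antigen CD61. Calls of both lists therefore include the sort itself. Without CD61+ replicate 1 the epithelial list turned downward (adjusted p = 0.0349) and the smooth muscle list lost its call (0.119). Without CXCR4+ replicate 1 the transition list (0.390) and the integrins (0.416) lost theirs, and without CXCR4+ replicate 2 the epithelial list turned downward with an adjusted p of 0.293. The difference of GRHL2 turned to -0.02 without CD61+ replicate 1, and that of CALD1 to -0.03 without CXCR4+ replicate 1.

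The other lists with an upward camera call had medians between 0.05 and 0.21. With an estimated correlation their adjusted p was 0.538, except 0.808 for extraembryonic endoderm and 0.780 for cholesterol synthesis. Trophoblast genes had medians of 0.21 and 0.03 within the replicates (adjusted p = 1.24e-05), with HAND1 at 2.02 and 0.19 and VTCN1 at 1.38 and 0.07. Mesoderm genes had medians of 0.10 and 0.00 (adjusted p = 0.000541), and extraembryonic endoderm genes 0.14 and 0.05 (adjusted p = 0.00444), with DAB2 at 0.64 and 0.64 and LAMC1 at 0.81 and 0.13. For p53 targets the medians were 0.22 and 0.13 (adjusted p = 1.8e-05), with RRM2B at 0.32 and 0.85 and PMAIP1 at 0.22 and 0.58. For hypoxia and glycolysis they were -0.04 and 0.28 (adjusted p = 0.000299), with P4HA2 at 0.18 and 1.01 and PDK1 at 0.23 and 0.81. Pluripotency genes had 0.05 and 0.22 (adjusted p = 0.00728), with PRDM14 at 0.08 and 0.94 and TERF1 at 0.16 and 0.76. Cholesterol synthesis genes had 0.04 and 0.22 (adjusted p = 0.00391), with MSMO1 at 0.52 and 0.39 and CYP51A1 at -0.04 and 0.77. Surface markers of early endoderm sorts had 0.14 and 0.10 (adjusted p = 1.24e-05), with CD44 at 0.46 and 0.66. Of all 15 calls, 6 held their direction and threshold without CD61+ replicate 1, 6 without CXCR4+ replicate 1, 8 without CXCR4+ replicate 2, 13 without CD61+ replicate 2 and 15 without the CXCR4+/CD61- array. The hypoxia list turned downward without CXCR4+ replicate 2 (adjusted p = 0.327). Without CXCR4+ replicate 1 the difference turned to -0.13 for LAMC1 and -0.21 for CD44, and without CD61+ replicate 2 to -0.22 for PRDM14 and -0.31 for CD44.

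The markers that define the sorted tissue did not separate CD61+ from CXCR4+ cells. The 27 measured definitive endoderm genes had a median difference of 0.00 (camera adjusted p = 0.591), with -0.23 in replicate 1 and 0.19 in replicate 2, and 6 of them were higher and 5 lower in both replicates. Ribosomal protein genes moved the same way, with medians of -0.16 in replicate 1, where 22 of 26 were lower, and 0.11 in replicate 2, where 21 of 26 were higher. The endoderm transcription factors SOX17 (-0.65 and 0.50) and FOXA2 (-0.36 and 0.21), both chosen after their values were seen, went opposite ways in the replicates. LHX1 was lower by -0.49 and -0.45 and APOA2 by -0.35 and -0.13 as signed differences, while FLRT3 differed by 0.31 and 0.74 and TRPA1 by 0.23 and 0.59. Neural and ectoderm genes had a downward call (median -0.19, camera adjusted p = 0.00607; adjusted p = 0.884 with an estimated correlation), which came from replicate 2. Their median was 0.08 in replicate 1 and -0.29 in replicate 2, where 19 of 20 were lower in CD61+ cells. PAX3, a neural crest factor, differed by -0.03 and -1.79, doublecortin (DCX) by 0.33 and -1.75, and NCAM1 by 0.37 and -1.66. Without CD61+ replicate 1 the neural call was lost (adjusted p = 0.200) and without CXCR4+ replicate 2 it turned upward (adjusted p = 1.55e-08). In both cases the direction was upward. DCX turned to 0.64 and NCAM1 to 0.25 without CD61+ replicate 1, and DCX to 1.68, NCAM1 to 1.27 and PAX3 to 0.84 without CXCR4+ replicate 2. LHX1, APOA2, SOX17 and FOXA2 turned upward without CXCR4+ replicate 1, to 0.12, 0.17, 0.48 and 0.35, and LHX1, APOA2 and FOXA2 without CD61+ replicate 2, to 0.09, 0.06 and 0.06.

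**Figure D2:**
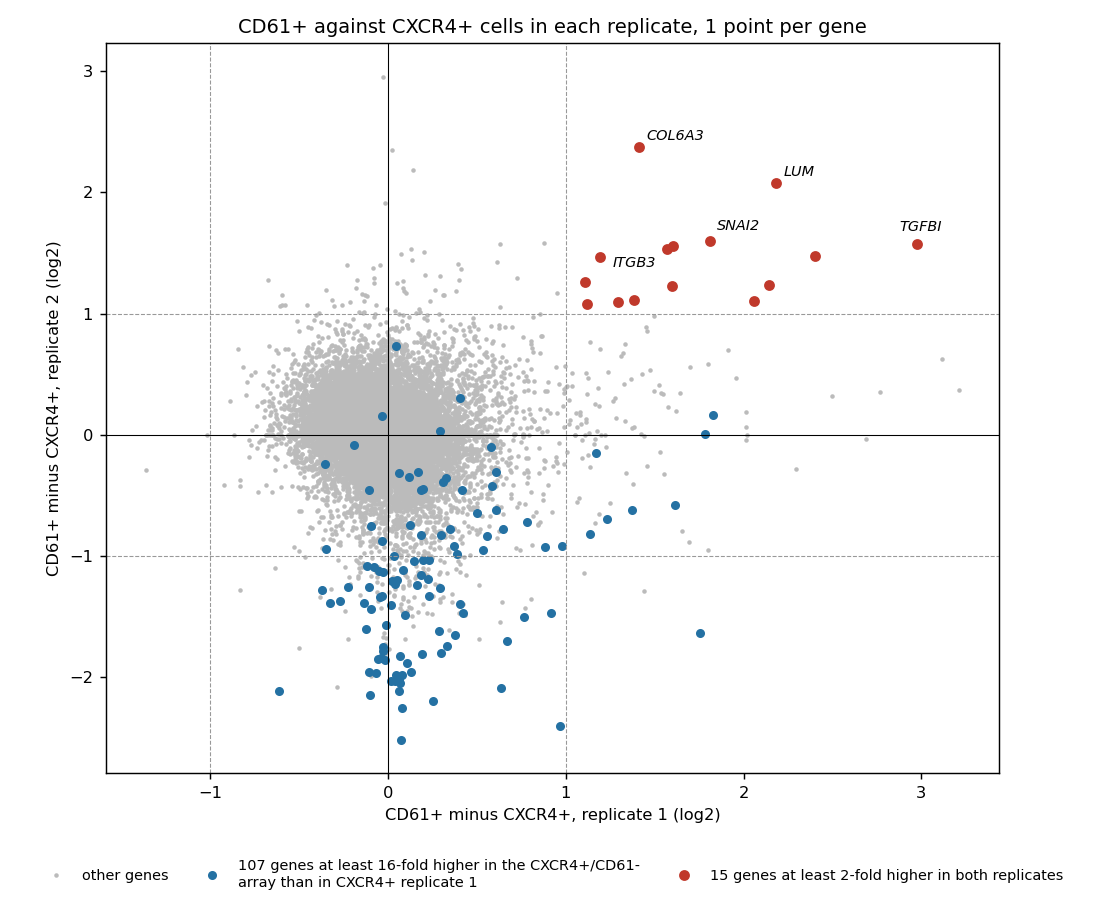
CD61+ minus CXCR4+ in replicate 1 (x axis, log2) and in replicate 2 (y axis, log2), with 1 point per gene for 18417 genes and dashed lines at 2-fold. The 15 genes in red were at least 2-fold higher in both replicates, and the 107 genes in blue were at least 16-fold higher in the CXCR4+/CD61- array than in CXCR4+ replicate 1, of which 101 lie below 0 on the y axis.

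CD61+ cells differed more from CXCR4+/CD61- cells than from CXCR4+ cells. The CXCR4+ label does not exclude CD61+ cells, so that sort may hold some of them. How far this accounts for the order was not tested. Within replicate 2, 496 genes were at least 2-fold higher and 459 at least 2-fold lower in CD61+ cells, against 76 and 199 in the comparison with CXCR4+ cells of the same replicate. This is 1 array against 1 with no replicate check, and the CXCR4+/CD61- sample had no replicate. Over the 5 arrays, and with the within-replicate 2 value second, the highest differences that met the rule for named genes were those of RAB25, an epithelial Rab protein (2.92 and 1.96), ERVH48-1, an endogenous retroviral gene (2.77 and 1.59), and CST1, a cystatin (2.70 and 2.44). ACTC1 (2.67 and 2.03), LUM (2.64 and 2.58), CDH1 (2.62 and 1.46) and HAPLN1 (2.51 and 2.00) followed. ZFP42 (2.53 and 2.27) and MIR302A (2.39 and 1.75), both markers of undifferentiated stem cells, were among the 12, with MAMDC2 (2.42 and 1.77), ELOVL7 (2.42 and 1.69) and EPCAM (2.30 and 2.37). Within replicate 2, ITGB3 was higher by 2.27. The matrix genes COL6A3 and COL1A1 were higher by 3.80 and 3.01 there, more than any of these 12. The order over the 5 arrays includes the gap between the replicates, since replicate 2 minus replicate 1 was -2.19 for RAB25 and -2.64 for ERVH48-1 in CD61+ and CXCR4+ cells. LUM, HAPLN1 and ELOVL7 were below 5 in CXCR4+/CD61- cells, so their differences are not exact sizes.

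Each of the 12 lowest genes was higher on every array of replicate 2 than on either array of replicate 1. DCX and MAP2 are members of the ectoderm and neural list, and MEIS1 and MEIS2 of the mesoderm list. The axon guidance receptor DCC was at 3.87 and 3.98 in CD61+ and CXCR4+ cells of replicate 1, and at 8.59, 10.55 and 10.96 in CD61+, CXCR4+ and CXCR4+/CD61- cells of replicate 2. Doublecortin (DCX) gave 4.68 and 4.35 in replicate 1 and 7.38, 9.13 and 10.03 in replicate 2. Within replicate 2, CD61+ minus CXCR4+/CD61- was -2.37 for DCC, -3.34 for the glycine receptor GLRA1, -2.97 for NSG2, -2.85 for TFAP2B, -2.65 for DCX, -2.56 for DNER, -2.30 for TAGLN3 and -2.22 for MAP2. It was -2.39 for MEIS2, -2.23 for MEIS1 and -2.08 for EPHA3. A2M, the protease inhibitor alpha-2-macroglobulin, stood apart, at 4.37 and 4.20 in replicate 1 and 11.23, 11.54 and 11.85 in replicate 2, a difference of -0.61 within replicate 2. Over the 5 arrays these differences lay between -4.00 and -4.73, which includes the gap between the replicates.

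By limma, 0 of 18417 genes passed between CD61+ and CXCR4+/CD61- cells, with a smallest adjusted p of 0.961 and 452 genes at an unadjusted p under 0.05 against 921 by chance. This fit counts the gap between replicates as spread, so the lower count does not show that the groups were alike. The lone array was assumed to vary like the other groups. The median of all genes was -0.21 as deposited, 0.02 after quantile normalization and -0.01 with a replicate term, so signed differences over the 5 arrays are to be read against that shift. With only the 2 groups compared, without either CXCR4+ array and without CD61+ replicate 2, some genes passed. Most of them were lower in CD61+ cells. More genes lay far higher in replicate 2 than far lower, and the CXCR4+/CD61- array belongs to replicate 2. These genes therefore cannot be told apart from the gap between the replicates. Without CD61+ replicate 1 no gene passed.

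In gene lists, camera called 21 of 30 between CD61+ and CXCR4+/CD61- cells, 18 upward and 3 downward. With an estimated correlation 0 lists were called (lowest adjusted p 0.312), and 0 with fry (lowest 0.718). Definitive endoderm genes were higher in CD61+ cells, with a median of 0.97 over the 5 arrays and 0.72 within replicate 2, where 26 of 27 were higher (camera adjusted p = 8.87e-24, adjusted p = 0.427 with an estimated correlation). Within replicate 2, SOX17 was higher by 1.01, FOXA2 by 0.85 and APOA2 by 1.34. Epithelial genes had medians of 1.32 and 1.09, with 20 of 20 higher in replicate 2 (camera adjusted p = 8.87e-24, adjusted p = 0.312 with an estimated correlation). CDH1 differed by 1.46, EPCAM by 2.37 and CLDN6 by 1.47 within replicate 2. In this list 7 members passed when adjusted over the list alone, among them EPCAM (adjusted p = 0.0176), and 0 over all genes. Of other lists, LUM passed in the matrix list alone (adjusted p = 0.00746) and EPCAM among surface markers (adjusted p = 0.0229). Within replicate 2 the median was 1.19 for the matrix list, 0.82 for smooth muscle, 0.68 for pluripotency, 0.64 for nodal and activin response, 0.61 for hypoxia and glycolysis, 0.61 for alpha-v beta-3 ligands and 0.35 for ribosomal proteins. Over the 5 arrays the medians were 0.46, 0.45, 0.64, 0.88, 0.54, 0.10 and 0.26. Camera on the 5 arrays gave adjusted p of 2.48e-06, 4.16e-07, 6.03e-08, 5.63e-07, 8.33e-10, 0.000474 and 0.000199. Of these lists, 11 of 14 nodal members and 8 of 18 ligands are also in other lists, so their calls are not separate results. Values of the upward lists over the 5 arrays, p-values included, also hold the gap between the replicates. Replicate 2 minus replicate 1 had a median of -0.44 over the endoderm list, -0.31 over the epithelial list, 0.97 over the matrix list and 0.41 over all genes. With a replicate block the medians of the 3 lists between CD61+ and CXCR4+/CD61- cells were 0.72, 1.19 and 1.05. Downward calls fell to ectoderm and neural genes (-0.41 within replicate 2, camera adjusted p = 0.000676), NOTCH response genes (-0.45, adjusted p = 0.00131) and replication-dependent histones (-0.55, adjusted p = 1.06e-05). These p-values belong to the fit over the 5 arrays. There the medians were -1.11, -1.0004 and -1.03, which include the gap between the replicates. Their adjusted p was 0.616, 0.638 and 0.607 with an estimated correlation. Primitive streak, mesoderm and integrin lists had an upward call and a median below 0 (-0.11, -0.04 and -0.09), as the median of all genes was -0.21. With each of the 4 CD61+ and CXCR4+ arrays left out in turn 14 of the 21 calls were kept every time. The lone CXCR4+/CD61- array could not be left out, and leaving out a CXCR4+ array changed only the spread. This count therefore does not show that the calls are stable. Without CD61+ replicate 2 the matrix list (adjusted p = 0.264), the ligands (0.0658), the transition list (0.353) and the integrins (0.180) lost theirs. The transition list also lost it without either CXCR4+ array (0.106), the stress list without CD61+ replicate 1 (0.0757), and the mesoderm and BMP lists with any 1 array left out (lowest adjusted p 0.0924 and 0.353).

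**Figure D3:**
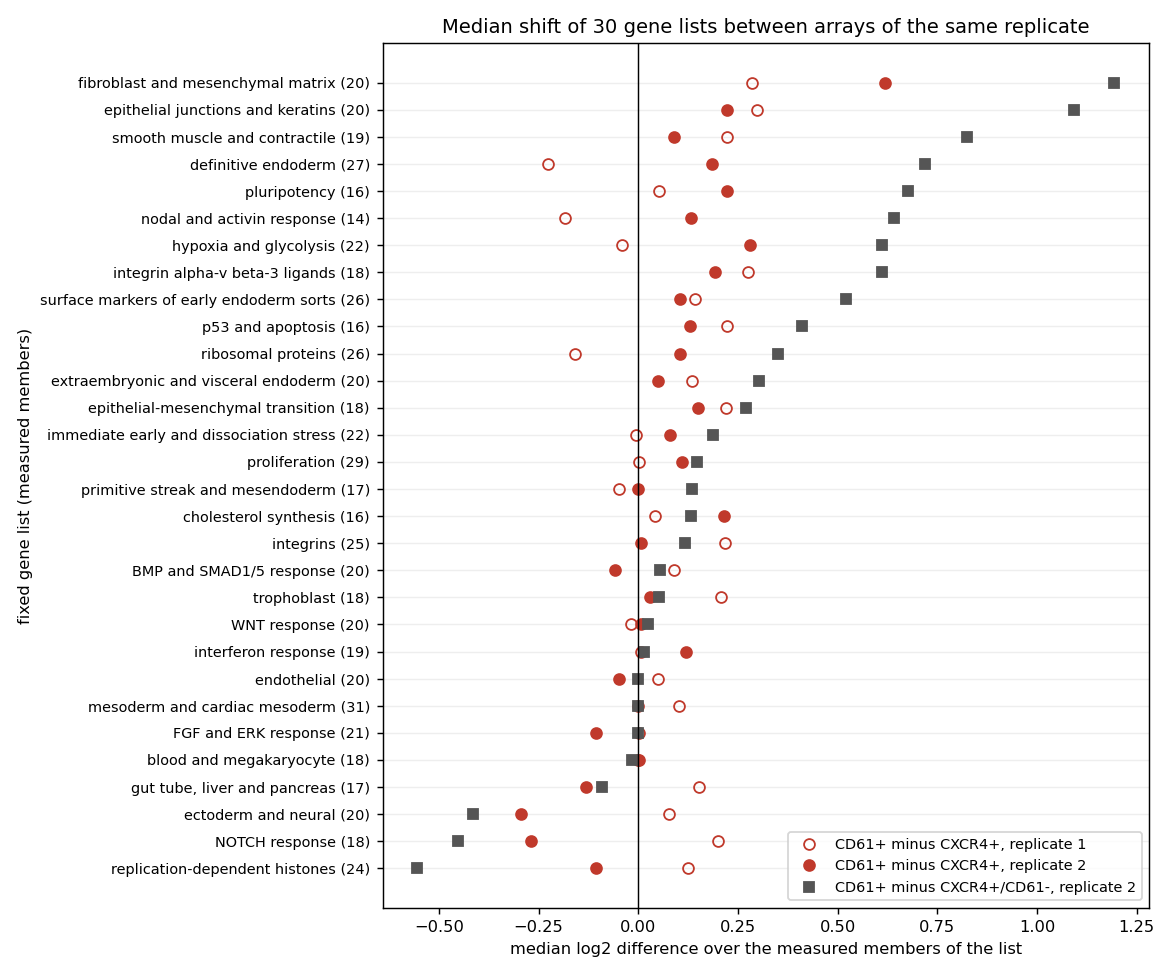
Median log2 difference (x axis) over the measured members of each of 30 fixed gene lists (y axis, with the number of members), with 1 point per pair of arrays of the same replicate. The matrix list lies at 0.29, 0.62 and 1.19, the definitive endoderm list at -0.23, 0.19 and 0.72, and the ectoderm and neural list at 0.08, -0.29 and -0.41.

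CXCR4+ cells held more mRNA of endoderm and epithelial genes than CXCR4+/CD61- cells of the same replicate. Within replicate 2, 178 genes were at least 2-fold higher and 36 at least 2-fold lower in CXCR4+ cells. The 5 highest over the 5 arrays, with the within-replicate 2 value second, were ERVH48-1 (2.92 and 1.46), RAB25 (2.55 and 1.32), CST1 (2.36 and 2.70), the natriuretic peptide gene NPPB (2.24 and 1.92) and ZFP42 (2.16 and 1.21), again with the gap between the replicates in the first value. The 5 lowest, A2M, MAP2, EPHA3, MEIS2 and DCC, lay between -3.69 and -3.98 over the 5 arrays and between -0.30 and -0.75 within replicate 2. Definitive endoderm genes had a median of 0.66 within replicate 2, with 25 of 27 higher (camera adjusted p = 4.15e-28), and epithelial genes one of 0.92 (camera adjusted p = 2.1e-20). Over the 5 arrays, to which the p-values belong, the medians were 1.02 and 1.09, which include the gap between the replicates. Both had an adjusted p of 0.365 with an estimated correlation. In all, camera called 15 of 30 lists, 12 upward and 3 downward, with 0 called with an estimated correlation (lowest adjusted p 0.365) and 0 with fry (lowest 0.898). Of the upward calls the primitive streak, extraembryonic endoderm and smooth muscle lists had a median below 0 (-0.11, -0.02 and -0.03). The downward calls were replication-dependent histones (median -0.41 within replicate 2, with 1 of 24 higher, camera adjusted p = 1.53e-07), NOTCH response genes (-0.17 within replicate 2, adjusted p = 0.00245) and neural genes (-0.06 within replicate 2, with 7 of 20 higher, adjusted p = 0.00808). Those p-values belong to the fit over the 5 arrays, where their medians were -0.99, -0.84 and -0.82 and include the gap between the replicates. With an estimated correlation their adjusted p was 0.679, 0.779 and 0.779. The 107 genes at least 16-fold higher in the CXCR4+/CD61- array than in CXCR4+ replicate 1 had a median of -0.59 within replicate 2, and all 107 were lower in CXCR4+ cells, having been picked for a high level in CXCR4+/CD61- cells. By limma 0 of 18417 genes passed, with 219 at an unadjusted p under 0.05 against 921 by chance in a fit that counts the gap between replicates as spread, and a median of all genes of -0.20. With only the 2 groups compared, and without either CD61+ array, the count was 58, and without CXCR4+ replicate 2 it was 611.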

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

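No gene passed in any comparison as deposited, and this held with a level filter, the mean of probe sets, every row of the table, quantile normalization, centring, an intensity trend, a robust prior, a looser threshold and a fold minimum. With only the 2 groups compared the count was 312 for CD61+ against CXCR4+/CD61- cells and 58 for CXCR4+ against CXCR4+/CD61- cells. With each array left out it ranged from 0 to 114 for CD61+ against CXCR4+ cells, from 0 to 326 for CD61+ against CXCR4+/CD61- cells and from 0 to 611 for CXCR4+ against CXCR4+/CD61- cells. For CD61+ against CXCR4+ cells, leaving out 1 array of either group makes the replicates unequal, so the gap between them enters the difference by construction. The other comparisons are unequal from the start. Leaving out an array of the group not compared changed only the spread there, and the cause of those counts was not tested. No label says what the replicate number marks. A replicate block gave 0 genes in each comparison (smallest adjusted p 0.698, 0.208 and 0.469), and 0 after quantile normalization. At an unadjusted p under 0.05 it gave 541 genes for CD61+ against CXCR4+ cells, 2337 for CD61+ against CXCR4+/CD61- cells and 1554 for CXCR4+ against CXCR4+/CD61- cells, against 921 by chance. Deviations from the group means correlated at r = 0.79 between arrays of the same number, with 2 pairs. A replicate block with an intensity trend, added after seeing the data, gave 1 gene for CD61+ against CXCR4+ cells (LUM, 2.13, adjusted p = 0.00311) and 2 for CD61+ against CXCR4+/CD61- cells (LUM, 2.61, and COL1A1, 3.08).

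The calls of gene lists rested on the preset correlation of camera. With an estimated correlation 0 lists were called for CD61+ against CXCR4+ cells, 0 for CD61+ against CXCR4+/CD61- cells and 0 for CXCR4+ against CXCR4+/CD61- cells, and with fry 0, 0 and 0. The cause was not tested. Both alternatives rest on 2 residual degrees of freedom, which leaves them little room to call any list. Neither was run on the simulated data, so the 0 counts do not show that no list differed. With a replicate block 15 and 20 calls kept their direction and threshold, and with the filtered background 13 and 19. With each array left out, the adjusted p for CD61+ against CXCR4+ cells ranged from 1.31e-21 to 0.200 for the neural list, from 3.79e-22 to 0.293 for the epithelial list and from 0.000299 to 0.725 for the hypoxia list, and each turned direction at least once.

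The differences of 71, 31 and 10 genes named in the report for the 3 comparisons kept their direction with quantile normalization, the mean of probe sets, a replicate block and centring. With each array left out, 25 of 355 values of the 71 genes printed for CD61+ against CXCR4+ cells turned direction, and 78 of 650 over all 130 eligible genes. For the other comparisons 0 did, which does not show stability. Genes named by size there were picked for arrays that do not overlap, so leaving 1 out cannot turn them. Leaving out an array of the group not compared leaves the difference as it was. The lone CXCR4+/CD61- array was never left out. The ranges were -0.52 to 0.24 for ITGA2B, -0.33 to 2.82 for COL1A1, -0.63 to 2.44 for THBS2, -0.78 to 2.56 for EDIL3, -0.020 to 1.83 for GRHL2, -0.033 to 1.60 for CALD1, -0.13 to 1.06 for LAMC1, -2.66 to 0.84 for PAX3, -3.10 to 1.68 for DCX, -0.22 to 1.24 for PRDM14, -2.55 to 1.27 for NCAM1, -0.31 to 1.43 for CD44, -1.06 to 0.12 for LHX1, -0.65 to 0.17 for APOA2, -0.63 to 0.48 for SOX17 and -0.50 to 0.35 for FOXA2.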

Other observations

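Each replicate had its own genes with large differences, chosen here after their values were seen. In replicate 1, CD61+ minus CXCR4+ was 2.30 for the calpain CAPN6 and 2.01 for collagen COL1A2, against -0.29 and 0.06 in replicate 2. In replicate 2 it was 2.96 for the collagenase MMP1, 2.35 for the thrombin receptor F2RL2, 2.18 for NT5E, a surface marker of mesenchymal stromal cells, 1.92 for EMP1 and 1.51 for periostin (POSTN), against -0.03, 0.02, 0.14, -0.02 and 0.20 in replicate 1. These 5 were below 4 on both arrays of replicate 1, close to the floor, so a difference there could have been missed. CXCR4+ exceeded CXCR4+/CD61- cells by 2.15 for MYOF, 2.05 for S100A14 and 1.76 for NOG.

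Other genes, also chosen after their values were seen, differed between the replicates. FABP7 and SOX2, both expressed in neural progenitors, were at 4.84 and 5.80 in CD61+ replicate 1 and at 10.59 and 10.08 in CD61+ replicate 2, and the hindbrain genes HOXA2 and HOXB2 at 3.24 and 3.95 against 6.94 and 7.40. The metallothionein MT1G went the other way, at 9.32 in CXCR4+ replicate 1 and 5.93 in CXCR4+ replicate 2. In all, 337 genes were at least 4-fold higher in replicate 2 and 4 at least 4-fold lower, and 175 and 14 after quantile normalization.

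All tests in this and the next 2 paragraphs were chosen after the values had been seen. The first pattern was 107 genes at least 16-fold higher in the CXCR4+/CD61- array than in CXCR4+ replicate 1, of which 5 are in the ectoderm and neural list and 9 in other lists. Separate normalization of the replicates could open such a gap. A first test on the neural list left this undecided (gap after joint quantile normalization 0.64, interval -0.04 to 1.66, bound 0.3). A second, chosen after it, on the 107 genes gave a median gap of 2.97 (quartiles 2.43 to 3.66), so that normalization did not remove their gap. These genes were picked for a gap of at least 16-fold on arrays that the test reuses. The size of their gap is therefore not a separate result. Sorted values differed by only 0.4353 to 0.4798 log2 on average between arrays of different numbers, far less than the gap left in these genes. This argues against a difference in distribution between the replicates as the cause of the gap in these 107 genes. Separate summarising of the probes was not tested. Neural cells in different shares could account for the pattern, but this stays open: that 94.4% of the 107 genes were lower in CD61+ than in CXCR4+ cells of replicate 2 restates the pattern, and the genes do not vary independently. The spread of the shifts, with a ratio of SDs of 1.94 against other genes, restates the unequal shifts of FABP7, A2M, SOX2 and DCC that prompted it and decides nothing about 1 population or several.

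The second pattern was the higher matrix genes of CD61+ cells. Fewer neural cells in the CD61+ sort could lift every other gene, which would shift other lists alike. In replicate 2, where neural genes were high, the matrix list lay above the definitive endoderm list by 0.43 (interval over genes of 1 array against 1, 0.18 to 0.92). The matrix list was taken up for its high shift, and both medians had been seen. This difference therefore describes 1 pair of arrays and does not decide the cause. The same difference in replicate 1, 0.51 (interval 0.24 to 1.20), decides nothing, since neural genes were low on both arrays. More mesenchymal cells in the sort may also raise them, and 75% of the list was higher in both replicates, between the bounds of 80 and 50 percent set for it, which left it undecided. RNA of any mouse feeder cells left after the sort on CD61 and CXCR4 could add to the same probe sets and was not tested, since probe sequences were not used here.

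The third pattern was the definitive endoderm list, lower in CD61+ cells of replicate 1 and higher in replicate 2. Neural RNA in the CXCR4+ array could dilute endoderm genes in replicate 2, where the list differed from the pluripotency and epithelial lists by -0.037 (interval -0.29 to 0.16), within the bound of 0.3. Those lists were chosen after their replicate 2 medians of 0.22 and 0.22 had been seen, so this does not decide the cause. The epithelial list also had 0.30 in replicate 1, where neural genes were low. Other lists went both ways in replicate 2, such as hypoxia at 0.28 and gut tube at -0.13. The replicate 1 shift of -0.23 was not tested, and ribosomal protein genes moved with the list in both replicates (-0.16 and 0.11).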
